A study of Mus musculus with 8 samples.

How the data were processed

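Single viable (7AAD-negative) cells from the livers of 8 mice were measured by droplet 3' RNA sequencing, with 1 library per mouse. The labels name a separate mouse for each library, and give 3 Control, 3 Partial Responder and 2 Resistant mice. The authors assigned the treated mice to the Partial Responder or Resistant group by tumour volume. According to the submitters' processing notes, reads were aligned and counted with Cell Ranger 3.1.0 against mm10 with vector sequences added. The deposited matrices of the authors hold a count of unique molecular identifiers (UMIs) per gene and cell barcode, as whole numbers that were not normalised. The 8 matrices held 6153 to 11437 barcodes and 47937139 to 91831518 UMIs. Counting error was the limit for genes with few UMIs, and a count of 0 allowed up to 3.

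Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept, 57525 in all. Doublets were scored against simulated pairs of cells, and the top share of each library, 0.8% per 1000 barcodes, was removed, 206 to 838 per library. Counts were scaled to 10000 per cell and put on a log scale. From 2000 variable genes, without mitochondrial, ribosomal, immunoglobulin and T cell receptor segment genes, 30 principal components and 20 nearest neighbours gave Leiden clusters at resolution 1, with no integration between libraries. This gave 39 clusters, and 22 and 20 finer ones within T or NK cells and within phagocytes. Clusters were named from 24 marker lists and levels of single markers, and names end in "-like" because no protein was measured. In 4 clusters no list of the class scored highest, and the name rested on levels: Cd8b1 at 1049 and 856.7 CPM in 1556 and 541 CD8 T-like cells (Cd4 1.648 and 0.7214), Cd4 at 170.1 in 1094 CD4 T-like cells (Cd8a 3.185) and Ace at 936.2 in 760 monocytes. Free RNA was not subtracted. In gene tests the CD4 T class includes regulatory T-like cells and cDC joins cDC1 and cDC2, while in shares of cells these are separate classes. Macrophages and monocytes were 1 class. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3. Gene positions came from GENCODE M21.

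UMIs were summed per class and library, for libraries with at least 20 cells of a class and groups with at least 2 such libraries, so that the mouse was the unit of replication. edgeR 4.0.16 fitted quasi-likelihood models with a mean per group over all libraries of a class, with TMM factors and genes kept by filterByExpr. The 3 comparisons were taken from that fit, and p-values were adjusted by Benjamini-Hochberg per class and comparison, with a threshold of 0.05. CPM values are group means over libraries. Sets of genes, 29 in all and written from general knowledge, were tested with camera at a preset correlation of 0.01 in limma 3.58.1, where at least 3 genes were tested, and adjusted over lists. Camera was repeated with an estimated correlation, and fry tested each set by itself. Of 636 list tests 234 passed at the preset correlation, 17 with an estimated one and 64 by fry, and the report gives the value with an estimated correlation. Shares of cells were compared with edgeR in the same design. The models were tested on simulated data with the library sizes and spread of the real ones, where macrophage and monocyte-like cells recovered 93.8% of genes changed 4-fold between Partial Responder and Control, and 3.64% to 12.3% of the calls were false over the classes and comparisons tested.

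Genes were named by a rule. It took, per class and comparison, the 4 largest rises and 4 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap between groups, without unnamed or receptor segment genes. By chance, 10% of genes do not overlap between 3 and 3 libraries and 20% between 2 and 3. It added up to 6 called members per list with the smallest p, and a fixed set that included Cxcl9, Cxcl10, Isg15, Irf7, Arg1, Spp1 and Mrc1 in macrophages, Gzmb, Ifng and Pdcd1 in CD8 T cells and Eomes, Il10, Foxp3, Lag3 and Ifng in CD4 T cells. The text gives part of the genes so chosen, and some are not reported here. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

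The alternatives were size factors by RLE in place of TMM, no filter on low counts, DESeq2 1.42.0 with its Wald test, the replicate number as a block, doublets kept, clusters at resolution 0.5, each library left out in turn, immune cells as the denominator of shares, exact permutation tests of shares, and an estimated correlation for list tests. Macrophages alone, monocytes alone, CD4 T-like cells without regulatory T cells, and a minimum of 5 cells for Kupffer-like and endothelial-like cells were added after the data were seen. When a Resistant library is left out, the remaining one is assumed to vary like the other groups.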

Results

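Livers of mice bearing colorectal cancer metastases were profiled as single cells in 8 droplet libraries, each from its own mouse. The 3 Control mice received a control lentiviral vector, and the 3 Partial Responder and 2 Resistant mice received a vector carrying interferon-alpha, a secreted cytokine that switches on antiviral genes. The authors split the treated mice by tumour volume, smaller than in Control mice in the Partial Responder group and similar to it in the Resistant group. The groups were therefore set by the outcome, and a comparison between them does not separate what precedes the outcome from what follows it. Library totals were 47937139, 57644694 and 53912525 UMIs in Control 1 to 3, 61503606, 69329716 and 57237084 in Partial Responder 1 to 3, and 73110761 and 91831518 in Resistant 1 and 2. After filters and the removal of 3509 barcodes scored as doublets, 54016 cells remained, from 4869 in Control 2 to 9398 in Resistant 2, with a median of 4592 to 6324 UMIs per cell. Marker genes placed the cells in 20 classes, and 5202 cells (9.63%) were left unnamed. B-like, T-like, NK or ILC1-like, phagocyte, hepatocyte-like, endothelial-like and epithelial tumour-like cells were among them. Free RNA in droplets gives every class some UMIs of genes that other cells express, so some marker genes of other cell types that moved with a group are given beside that group's genes.

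No UMI was assigned to the interferon-alpha transgene. Its sequence, mIFN, had 0 UMIs in each of the 8 libraries, where a count of 0 allows up to 3 UMIs. Whether the sequence in the authors' reference reaches the 3' end of the vector transcript, where the reads lie, is not known, so that this count does not show that the transgene was absent. Mouse Ifna genes gave 0 UMIs in Control and 3 in treated libraries, and Ifnb1 gave 1 and 5.

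Partial Responder livers were first compared with Control livers, which asks what differed where the interferon-alpha vector went with a smaller tumour volume. Interferon response genes were higher in the 7 immune classes tested of Partial Responder livers, with a median change across the list of 1.41 to 2.73 on the log2 scale. Macrophage and monocyte-like cells had the most called genes, and 13 of 17 MHC class I genes rose in them (list adjusted p = 0.0977 with an estimated correlation) while Fn1 fell. CD8 T-like and CD4 T-like cells changed in fewer genes, and 31 of 100 called genes in the former and 33 of 97 in the latter were members of the interferon response list. Endothelial-like and cDC2-like cells took a larger share of the cells, calls that rested on particular Control libraries. In epithelial tumour-like cells edgeR called 0 genes and DESeq2 13.

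The interferon response list, fixed from general knowledge of type I interferon targets, was higher in each of 7 immune classes with an estimated correlation between genes too. The called members, all higher, were 35 of 35 in B-like cells (35 when adjusted over the list alone; list adjusted p = 0.000366 with an estimated correlation), 33 of 33 in NK or ILC1-like cells (33; 0.000103), 33 of 35 in neutrophil-like cells (35; 0.000136) and 33 of 34 in CD4 T-like cells (34; 0.000516). They were 34 of 35 in macrophage and monocyte-like cells (35; 0.0192), 31 of 34 in CD8 T-like cells (34; 0.00511) and 30 of 35 in cDC-like cells (35; 0.00775). Hepatocyte-like cells, with 3 Partial Responder and 2 Control libraries, had 4 called of 26 (19 when adjusted over the list alone; adjusted p = 0.217 with an estimated correlation). Irf7, the transcription factor that amplifies interferon production (ENSMUSG00000025498, mm10 chromosome 7, 141262706 to 141266481, minus strand), rose by 2.95 ± 0.12 on the log2 scale (SE) in macrophage and monocyte-like cells (adjusted p = 2.65e-06). It rose by 3.24 ± 0.10 in B-like, 3.02 ± 0.12 in NK or ILC1-like, 2.91 ± 0.16 in neutrophil-like and 2.69 ± 0.10 in cDC-like cells, with adjusted p of 4.66e-10, 1.05e-09, 7.04e-05 and 1.48e-07. In each of these classes the list's mean in every treated library lay above that in every Control library.

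**Figure D1:**
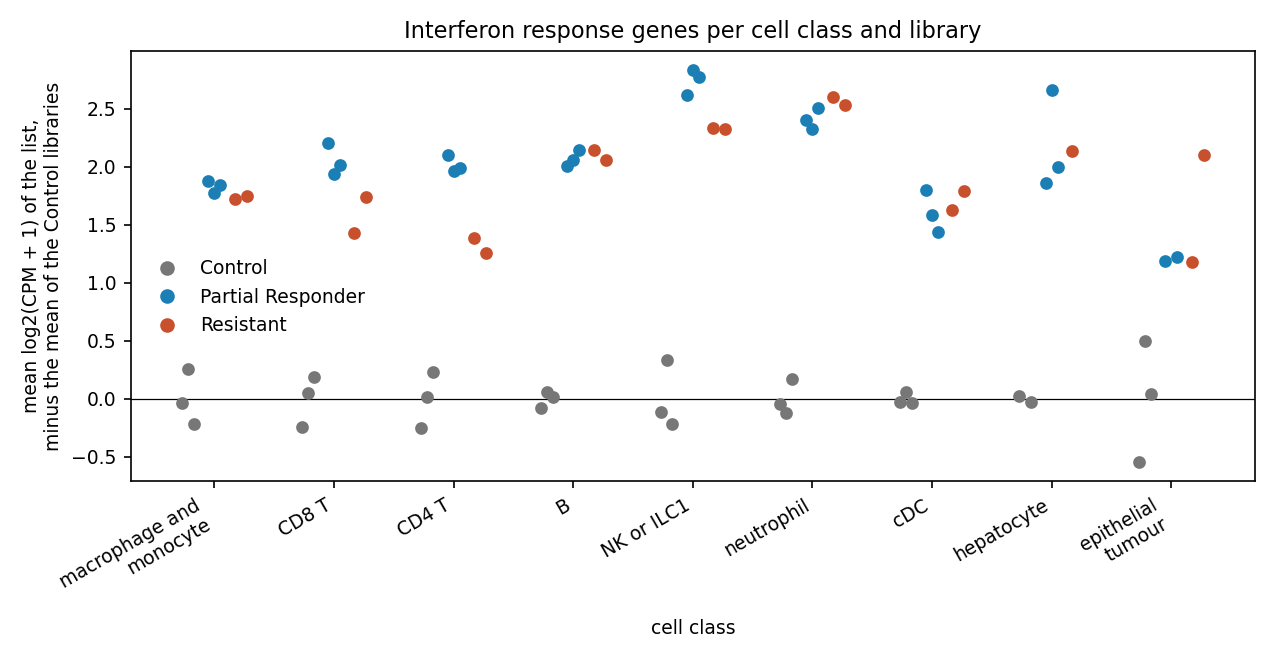
Mean log2(CPM + 1) of the interferon response genes minus the mean of the Control libraries (y axis) for 9 cell classes (x axis), with 1 point per library coloured by group. In each class every treated library with enough cells, 5 of 5 or 4 of 4, lay above every Control library, by 1.18 to 2.83 over the Control mean.

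Among macrophage and monocyte-like cells 1089 of 10368 genes differed between Partial Responder and Control livers, 642 higher and 447 lower, at an adjusted p under 0.05. The count was 524 without Control 3, and 638, 613 and 705 without Partial Responder 1, 2 and 3. Ifi44, an interferon-induced antiviral gene, rose by 6.03 ± 0.31 (adjusted p = 5.01e-06), Ly6a, a surface antigen, by 4.77 ± 0.35 (adjusted p = 3.66e-05) and Csprs by 4.58 ± 0.31 (adjusted p = 2.04e-05). Irf7 went from 197 ± 26.8 to 1518 ± 120 CPM (SD, n = 3 and 3), a fold of 7.70. Isg15, a ubiquitin-like modifier (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818, minus strand), went from 157 ± 76.5 to 809 ± 151 CPM, a log2 change of 2.37 ± 0.33 (adjusted p = 0.00201). Of 17 MHC class I presentation genes 13 rose (16 when adjusted over the list alone), among them H2-Q6 by 3.98 ± 0.28, H2-K1 by 1.57 ± 0.12 and B2m by 0.95 ± 0.09, while the list had an adjusted p = 0.0977 with an estimated correlation. Reads of H2-Q6 and its near-identical relatives are hard to tell apart. Of 20 interferon-gamma-inducible GTPases and chemokines 8 rose (10 when adjusted over the list alone), such as Iigp1 by 3.62 ± 0.39 and Gbp6 by 3.00 ± 0.41, with an adjusted p = 0.576 for the list with an estimated correlation. Most Control cells of the class lay in 1 monocyte-like cluster, with 163, 334 and 359 cells in Control 1 to 3 and at most 8 in any treated library.

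Chemokines and macrophage-state genes gave a mixed picture in the same cells. Ccl7, a monocyte attractant (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525, plus strand), rose from 4.19 ± 2.44 to 96.7 ± 85.7 CPM, a log2 change of 4.41 ± 0.90 (adjusted p = 0.0155). Without Control 2 or Control 3 its adjusted p was 0.0572 and 0.0529 (7.98e-05 to 0.0903 over its alternatives). Ccl2 rose by 2.67 ± 0.53 (adjusted p = 0.0142; 0.0512 without Control 2 and 0.0647 without Control 3; 0.000764 to 0.768 over its alternatives). Nos2, the inducible nitric oxide synthase, had 92 UMIs in Partial Responder and 0 in Control libraries, at least 16.3-fold higher over a floor of 3 counts for the group (adjusted p = 0.0240). That call was lost without Control 2 (0.0543), Control 3 (0.0851), Partial Responder 1 (0.0512) or Partial Responder 2 (0.0585), with 2.91e-05 to 0.0903 over its alternatives. Ccl2, Nos2 and Cd86 were the 3 called of 15 inflammatory macrophage genes (3 when adjusted over the list alone), a list whose median lay below 0 and whose mean lay above it (adjusted p = 0.683, and 0.856 with an estimated correlation). Cxcl10, a T cell attractant, changed by 0.27 ± 1.11 (adjusted p = 0.916), and Control 2 decided that value: Control 1 to 3 stood at 27.3, 1037 and 20.7 CPM, and without Control 2 the change was 4.21 (adjusted p = 9.74e-05; 9.74e-05 to 0.980 over its alternatives). Cxcl9 changed by -0.71 ± 0.68 (adjusted p = 0.556). Of 9 p53 targets 3 rose (5 when adjusted over the list alone; list adjusted p = 0.336 with an estimated correlation), namely Phlda3 by 2.70 ± 0.44, Bbc3 by 0.75 ± 0.11 and Cdkn1a by 1.12 ± 0.24. The Cdkn1a call (adjusted p = 0.0189) was lost without Control 3 (0.0616), Partial Responder 1 (0.0538) or Partial Responder 2 (0.0633), with 2.01e-05 to 0.293 over its alternatives.

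Pro-tumour macrophage genes did not move as a list. Of 18 only Fn1, a marker of the Control monocyte-like cluster, was called (1 over the list alone) and fell by 2.65 ± 0.23 (adjusted p = 9.39e-05). Arg1 changed by 0.42 ± 0.90 (adjusted p = 0.823), Spp1 by -0.53 ± 0.66 (0.669) and Mrc1 by -0.31 ± 0.65 (0.820). The list itself had an adjusted p = 0.106, called without Control 2 (0.00632) or Partial Responder 2 (0.0204), and 0.75 with an estimated correlation (0.00126 to 0.75 over its alternatives). Saa3 fell by 2.90 ± 0.72 (adjusted p = 0.0340), a call lost without Control 1 (0.0804), Control 2 (0.0603), Partial Responder 1 (0.0747), Partial Responder 2 (0.104) or Partial Responder 3 (0.0922), with 0.00218 to 0.194 over its alternatives. The near-identical haemoglobin genes Hba-a1 and Hba-a2 fell by 2.86 ± 0.52 and 2.81 ± 0.51, and 4 of 5 erythroid genes, markers of red cells rather than phagocytes, fell (5 when adjusted over the list alone; list adjusted p = 0.547 with an estimated correlation). Other markers rose in these cells, the lymphocyte receptor Klrk1 by 2.34 ± 0.30 (adjusted p = 0.00114) and the hepatocyte gene Alb by 1.53 ± 0.29 (adjusted p = 0.0101; 0.0501 without Control 3).

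CD8 T-like cells differed in 100 of 10121 genes, 92 higher and 8 lower (DESeq2 called 183). The count was 63 without Control 1 and 215 without Partial Responder 2. Ifi44 rose by 4.91 ± 0.53 (adjusted p = 0.000929), Ifit3 and its paralog Ifit3b, which share much of their sequence, by 3.42 ± 0.25 and 3.57 ± 0.35, Rsad2 by 3.24 ± 0.28, Ifi27l2a by 3.06 ± 0.15 (adjusted p = 2.52e-05) and Usp18 by 2.72 ± 0.17. Isg15 rose from 31.8 ± 6.61 to 211 ± 58.0 CPM, a log2 change of 2.75 ± 0.26 (adjusted p = 0.000386). Of 19 interferon-gamma-inducible genes 4 rose (11 when adjusted over the list alone), including Gbp6 by 1.94 ± 0.15 and Irgm1 by 1.21 ± 0.15, and the list had an adjusted p = 0.0767 with an estimated correlation. Of 17 MHC class I genes 1 rose (5 when adjusted over the list alone; adjusted p = 0.175 with an estimated correlation). Tnf rose by 2.23 ± 0.35 (adjusted p = 0.0118; 0.119 without Control 1 and 0.0544 without Partial Responder 1; 4.09e-08 to 0.119 over its alternatives). Effector genes did not pass: Gzmb, granzyme B, changed by 0.65 ± 0.35 (adjusted p = 0.588) and Ifng by -0.31 ± 0.60 (0.912). Pdcd1, which encodes the inhibitory receptor PD-1, changed by -1.46 ± 0.52 (adjusted p = 0.396) and by -2.17 without Partial Responder 2 (adjusted p = 0.0474; 0.00850 to 0.729 over its alternatives). None of 13 checkpoint and exhaustion genes passed (0 when adjusted over the list alone; list adjusted p = 0.558 with an estimated correlation). CD8 T-like cells came from different clusters in the groups, with 604, 233 and 114 cells of a cluster in Partial Responder 1 to 3 and 12, 15 and 3 in Control 1 to 3.

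The genes with the largest falls in CD8 T-like cells each rested on particular libraries. Tcrg-C4 fell by 1.37 ± 0.23 (adjusted p = 0.0166; 0.130 without Control 1, 0.0749 without Control 2 and 0.0645 without Partial Responder 1; 4.19e-05 to 0.474 over its alternatives). Eomes, a transcription factor of effector and memory T cells (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132, plus strand), fell by 0.93 ± 0.17 (adjusted p = 0.0270). Its call was lost without Control 1 (0.160), Control 3 (0.0877), Partial Responder 1 (0.126) or Partial Responder 3 (0.0662), with 0.000199 to 0.160 over its alternatives. Vps37b fell by 0.66 ± 0.13 (adjusted p = 0.0405) and Tspan13 by 0.62 ± 0.12 (adjusted p = 0.0371). For Vps37b the adjusted p was 0.229 without Control 1, 0.192 without Control 3, 0.187 without Partial Responder 1 and 0.0766 without Partial Responder 3 (0.00157 to 0.229 over its alternatives). For Tspan13 it was 0.194 without Control 1, 0.0690 without Control 2, 0.175 without Control 3, 0.181 without Partial Responder 1 and 0.111 without Partial Responder 3 (0.00449 to 0.194 over its alternatives).

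Within CD4 T-like cells, regulatory T-like cells included, 97 of 9553 genes differed, 92 higher and 5 lower. Ifi44 rose by 4.54 ± 0.45 (adjusted p = 0.000218), Ifit3 by 3.98 ± 0.24, Rtp4 by 2.62 ± 0.13 (adjusted p = 7.13e-06) and Irf7 by 2.56 ± 0.16. Isg15 rose from 44.9 ± 13.5 to 254 ± 66.2 CPM, a log2 change of 2.52 ± 0.27 (adjusted p = 0.000415). Of 17 MHC class I genes 4 rose (8 when adjusted over the list alone; list adjusted p = 0.126 with an estimated correlation), H2-T22 by 0.94 ± 0.13. Of 19 interferon-gamma-inducible genes 3 rose (7 when adjusted over the list alone), Irgm1 by 1.20 ± 0.15, with an adjusted p = 0.0149 for the list with an estimated correlation. The regulatory and effector genes Eomes (log2 change -0.95 ± 0.57, adjusted p = 0.865), Il10 (1.21 ± 0.72), Foxp3 (-0.64 ± 0.32, 0.806) and Lag3 (-0.71 ± 0.40, 0.859) did not pass. Ifng changed by -0.03 ± 0.47 (adjusted p = 1), and by -1.12 without Partial Responder 2, where its adjusted p was 0.0291. Of the 5 genes that fell, 4 were named by the rule, Trf by 1.62 ± 0.32 (adjusted p = 0.0393), Fos by 1.34 ± 0.27 (0.0411), Fosb by 1.06 ± 0.21 (0.0431) and Ifi27 by 0.91 ± 0.18 (0.0355), and none of these calls was steady to leaving out a library. Trf had an adjusted p of 0.258, 0.109 and 0.138 without Control 1, 2 and 3, 0.144 and 0.0916 without Partial Responder 2 and 3, and 0.0502 and 0.0529 without Resistant 1 and 2. Fos had 0.266, 0.0895 and 0.121 without Control 1, 2 and 3, 0.143 without Partial Responder 2 and 0.0502 without Resistant 2. Fosb had 0.0786, 0.263 and 0.172 without Control 1, 2 and 3 and 0.142, 0.115 and 0.128 without Partial Responder 1, 2 and 3. Ifi27 had 0.192, 0.173 and 0.0817 without Control 1, 2 and 3 and 0.175 and 0.112 without Partial Responder 1 and 3. Over all alternatives the adjusted p of Trf, Fos, Fosb and Ifi27 reached up to 0.931, 0.266, 0.877 and 0.192.

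No gene passed in epithelial tumour-like cells, where Partial Responder 2 and 3 were compared with 3 Control libraries. Partial Responder 1 had 0 of 7437 cells in this class, which allows a share of up to 0.0403%. At an unadjusted p under 0.05 there were 372 of 10013 genes, and DESeq2 called 13. The test recovered 55.1% of simulated genes at a 4-fold change and 10.2% at 2-fold. Of 35 interferon response genes 34 had a positive change and 0 passed, or 18 when adjusted over the list alone (median 1.10, list adjusted p = 0.251 with an estimated correlation). Isg15 had 141 ± 5.45 CPM against 43.4 ± 22.9 in Control, a log2 change of 1.77 ± 0.36 (adjusted p = 0.587). The MHC class I list had 14 of 17 genes with a positive change and 0 called (0 when adjusted over the list alone). Its adjusted p was 0.541 with an estimated correlation, and its call at the preset correlation was lost without Control 1 (0.0598), with 1.53e-05 to 0.541 over its alternatives. H2-K1 changed by 0.45 ± 0.21, B2m by 0.32 ± 0.21 and the proliferation gene Mki67 by 0.46 ± 0.31, none past the threshold.

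The other immune classes rose in interferon genes as well as in genes outside that list. B-like cells had 231 of 10945 genes called (200 higher, 31 lower), with Ifit3 up by 3.35 ± 0.10 (adjusted p = 4.66e-10). They came mostly from 1 cluster in Control libraries (2660, 1364 and 2260 cells in Control 1 to 3) and from another in treated ones. NK or ILC1-like cells had 191 of 9227 (171 higher, 20 lower; 127 without Control 1), with Ifi27l2a up by 5.98 ± 0.21 and Gzmb by 0.59 ± 0.09 (adjusted p = 0.00147). Neutrophil-like cells had 80 of 8843 (77 higher, 3 lower; 35 without Control 1 and 48 without Partial Responder 3), with Ifit3 up by 4.89 ± 0.29 (adjusted p = 8.04e-05). cDC-like cells had 208 of 9436 (171 higher, 37 lower; 136 without Control 1 and 137 without Partial Responder 2). The p53 targets Phlda3 and Cdkn1a rose there by 2.86 ± 0.43 and 1.14 ± 0.19, while Cd209d fell by 3.97 ± 0.29 (adjusted p = 3.41e-05) and the chemokine gene Ccl22 by 2.77 ± 0.49 (adjusted p = 0.0122). Of 8 p53 targets in cDC-like cells 4 rose (7 when adjusted over the list alone; list adjusted p = 0.0599 with an estimated correlation). MHC class I genes rose in 10 of 17 in B-like (adjusted p = 0.0522 with an estimated correlation), 11 of 17 in NK or ILC1-like (0.0228), 8 of 17 in cDC-like (0.0599) and 5 of 17 in neutrophil-like cells (0.349). Hepatocyte-like cells had 12 of 4474 called (9 higher, 3 lower; 0 without Control 2, Partial Responder 1 or Partial Responder 2, and 4 without Resistant 1), all at an adjusted p of 0.0358 for those named. Ifi27l2a rose by 4.01 ± 0.62 and Irf7 by 2.52 ± 0.39, and so did the B cell gene Ly6d, by 2.74, chosen after its values were seen, whereas Dnajc12 fell by 2.07 ± 0.31 and Hbb-bt, a red-cell gene, by 5.94 ± 0.95.

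Shares of cells changed in 2 classes between Partial Responder and Control livers. Endothelial-like cells made up 2.40% ± 1.24 (SD, n = 3) against 0.177% ± 0.188 (n = 3), a log2 change of 3.76 ± 1.02 (adjusted p = 0.0424). cDC2-like cells made up 3.96% ± 2.28 against 0.781% ± 0.257, a log2 change of 2.34 ± 0.58 (adjusted p = 0.0424). Leaving out a library ended both calls, at 0.182 without Control 1 and 0.244 without Control 3, and the cDC2 call also at 0.0508 without Partial Responder 1 (0.00581 to 0.244 and 0.00153 to 0.244 over their alternatives). An exact permutation test of 3 against 3 libraries cannot go below a two-sided p of 0.1. CD8 T-like cells took 11.2% ± 3.40 against 6.29% ± 1.96 without passing (adjusted p = 0.412), and cDC1-like cells 1.82% ± 0.213 against 0.668% ± 0.382 (adjusted p = 0.132; 0.0186 without Control 2; 0.0186 to 0.510 over its alternatives). Epithelial tumour-like cells made up 0.569% ± 0.671 against 1.19% ± 0.164, which did not pass.

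**Figure D2:**
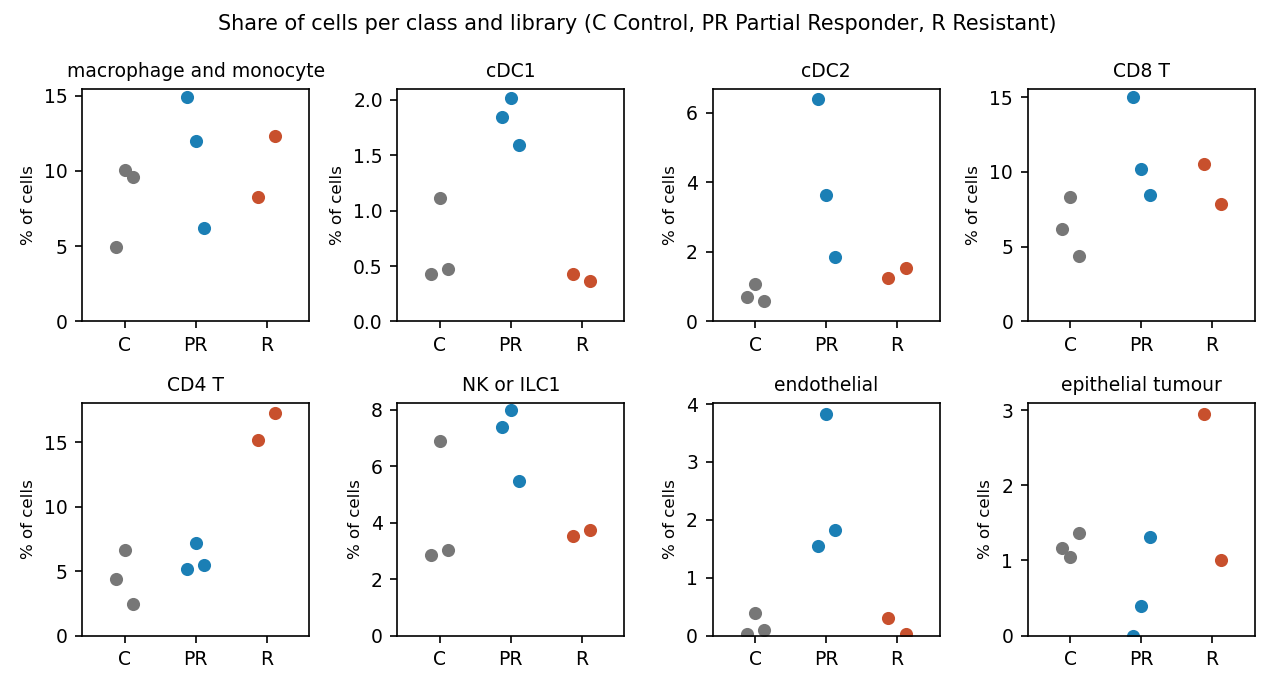
Share of all cells in percent (y axis) per group (x axis), with a panel for each of 8 cell classes and 1 point per library. Endothelial-like cells averaged 2.40% in Partial Responder and 0.177% in Control livers, and CD4 T-like cells, without regulatory T-like cells, 16.2% in Resistant and 4.47% in Control livers.

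Resistant livers were then compared with the same Control livers, which asks what differed where the vector did not go with a smaller tumour volume. The interferon response was again higher in every immune class tested. CD4 T-like cells differed in many more genes than in Partial Responder livers, with Gzmk, Eomes, Il10 and 7 of 16 cytotoxic genes higher and 9 of 10 naive or memory genes lower (list adjusted p = 0.169 and 0.144 with an estimated correlation). Macrophage and monocyte-like cells changed in about as many genes as in Partial Responder livers, with Ccl7 and Ccl2 higher. In epithelial tumour-like cells Krt17 was lower and Ccl2 higher. No share of cells passed.

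In Resistant livers the interferon response list was called at 35 of 35 in B-like cells (35 when adjusted over the list alone; list adjusted p = 0.000295 with an estimated correlation), 34 of 35 in neutrophil-like (35; 0.000184), 33 of 35 in macrophage and monocyte-like (35; 0.0309), 31 of 35 in cDC-like (34; 0.00893). It was called at 29 of 34 in CD4 T-like (30 higher and 1 lower; 0.0387), 28 of 34 in CD8 T-like (32; 0.00597) and 28 of 33 in NK or ILC1-like cells (32; 8.47e-05). Irf7 rose by 3.33 ± 0.10 in B-like (adjusted p = 5.92e-10) and 3.15 ± 0.17 in neutrophil-like (8.24e-05) cells.

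The macrophage and monocyte-like cells of Resistant livers differed from Control in 950 of 10368 genes, 590 higher and 360 lower. The count was 492 without Control 3, 292 without Resistant 1 and 452 without Resistant 2. Ccl7 rose 71.0-fold, from 4.19 ± 2.44 to 329 ± 239 CPM (log2 change 6.15 ± 0.95, adjusted p = 0.00460), and Ccl2 by 3.74 ± 0.58 (adjusted p = 0.00466). Ccl12 rose by 4.20 ± 0.89 (adjusted p = 0.0207; 0.0551 without Control 1, 0.0846 without Control 3, 0.0738 without Resistant 1 and 0.0654 without Resistant 2; 0.000528 to 0.0922 over its alternatives). Nos2 had 126 UMIs against 0 in Control, at least 34.6-fold higher over the same floor (adjusted p = 0.0131). Ifi44 rose by 5.92 ± 0.31, Ly6a by 4.54 ± 0.36, Isg15 by 2.25 ± 0.35 (746 ± 210 CPM, adjusted p = 0.00466) and Irf7 by 2.78 ± 0.13 (adjusted p = 7.83e-06). Of 17 MHC class I genes 12 rose (15 when adjusted over the list alone; adjusted p = 0.0988 with an estimated correlation), H2-Q6 by 3.93 ± 0.30, H2-K1 by 1.42 ± 0.13 and B2m by 0.85 ± 0.09. Of 20 interferon-gamma-inducible genes 8 rose (11 when adjusted over the list alone; adjusted p = 0.332 with an estimated correlation), Iigp1 by 3.82 ± 0.41 and Gbp6 by 3.02 ± 0.42. Havcr2, an inhibitory receptor, rose by 1.44 ± 0.11 (adjusted p = 4.81e-05). Of 9 p53 targets 2 rose (5 when adjusted over the list alone; adjusted p = 0.308 with an estimated correlation), Phlda3 by 2.76 ± 0.46 and Cdkn1a by 1.68 ± 0.26. Hist1h1d fell by 1.86 ± 0.32 (adjusted p = 0.00817; 0.0771 without Resistant 1).

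Macrophage-state genes again split. Of 18 pro-tumour macrophage genes Fabp5 rose by 1.18 ± 0.20 (adjusted p = 0.00775; 0.0529 without Resistant 2). The cluster marker Fn1 fell by 1.59 ± 0.25 (adjusted p = 0.00549), with 5 higher and 1 lower over the list alone. The list's adjusted p was 0.0395, lost without Control 2 (0.273) or Resistant 1 (0.585), and 0.595 with an estimated correlation (0.00111 to 0.801 over its alternatives). Arg1 changed by 2.41 ± 1.00 (adjusted p = 0.164), Spp1 by 0.71 ± 0.73 (0.586) and Mrc1, the mannose receptor, by 2.13 ± 0.65 (0.0705; a change of 2.87 at 0.0182 without Resistant 2; 0.0174 to 0.586 over its alternatives). The inflammatory list, with Ccl2, Nos2 and Cd86 called of 15 (3 when adjusted over the list alone), had an adjusted p = 0.00751, lost without Control 3 (0.0692) or Resistant 1 (0.148), and 0.45 with an estimated correlation (2.05e-05 to 0.45 over its alternatives). Cxcl10 changed by -0.01 ± 1.24 (adjusted p = 0.997) and by 3.94 without Control 2 (0.000203; 0.000203 to 1 over its alternatives), and Cxcl9 by -1.34 ± 0.79 (0.324). RNA of other cell types moved in these cells as well. Of 5 erythroid genes 2 fell (3 when adjusted over the list alone; list adjusted p = 0.435 with an estimated correlation; calls at the preset correlation lost without Control 2 at 0.0668 and Resistant 1 at 0.0774), Hba-a1 by 2.22 ± 0.59 and Hba-a2 by 2.19 ± 0.57. Their adjusted p of 0.0472 and 0.0453 were both lost without Control 1, Control 2, Partial Responder 2, Partial Responder 3, Resistant 1 or Resistant 2 at 0.0619 to 0.250 (0.00520 to 0.532 over their alternatives). Of 8 T cell genes 2 rose (4 when adjusted over the list alone; adjusted p = 0.332 with an estimated correlation). Trac rose by 2.54 ± 0.54 (adjusted p = 0.0209; 0.0708 without Control 3, 0.114 without Resistant 1 and 0.0589 without Resistant 2, and a change of 3.93 without Control 2). Of 5 epithelial genes 1 rose (4 when adjusted over the list alone; 0.332), Krt18 by 1.89 ± 0.37 (adjusted p = 0.0141; 0.112 without Resistant 1).

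**Figure D3:**
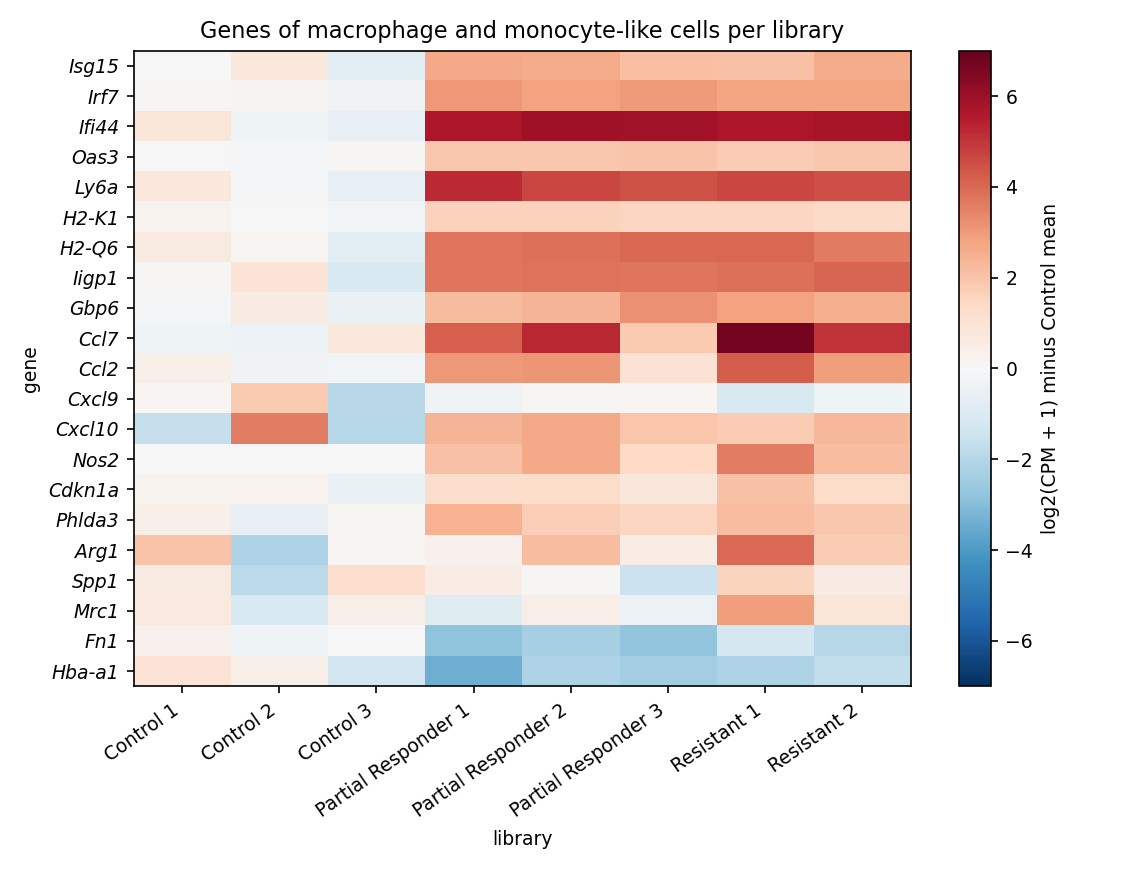
Change of log2(CPM + 1) from the Control mean (colour) for genes (y axis) in macrophage and monocyte-like cells of each library (x axis). Irf7, Ifi44 and H2-K1 were higher in all 5 treated libraries, whereas Cxcl10 was highest in Control 2.

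CD8 T-like cells of Resistant livers differed from Control in 49 of 10121 genes, all higher. The count was 22 without Control 1, 23 without Control 2, 28 without Control 3 and 29 without Resistant 2. Ifi27l2a rose by 2.86 ± 0.16 (adjusted p = 7.44e-05), Ifit3 by 2.59 ± 0.26 and Irf7 by 2.19 ± 0.17 (adjusted p = 0.000634). Ly6a rose by 2.99 ± 0.39 (adjusted p = 0.00749; 0.0982 without Control 1) and Gbp6 by 1.32 ± 0.16 (adjusted p = 0.00588; 0.0502 without Control 1). Isg15 rose by 1.78 ± 0.27 (adjusted p = 0.0172), a call lost without Control 1 (0.151), Control 2 (0.125), Control 3 (0.0584) or Resistant 2 (0.12), with 2.47e-08 to 0.166 over its alternatives. Gzmb changed by 1.29 ± 0.38 (adjusted p = 0.599; 0.00355 to 1 over its alternatives), Ifng by 0.70 ± 0.65 and Pdcd1 by 0.13 ± 0.56, none past the threshold. None of 13 checkpoint and exhaustion genes and none of 17 MHC class I genes passed (0 and 3 when adjusted over the list alone; list adjusted p = 0.804 and 0.155 with an estimated correlation), and 1 of 19 interferon-gamma-inducible genes did (5 when adjusted over the list alone; 0.155).

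CD4 T-like cells of Resistant livers differed from Control in 945 of 9553 genes, 485 higher and 460 lower. The count was 482, 426 and 487 without Control 1, 2 and 3, and 599 and 294 without Resistant 1 and 2. Gzmk, a granzyme (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908, minus strand), rose from 51.8 ± 5.87 to 598 ± 104 CPM (SD, n = 3 and 2), a log2 change of 3.52 ± 0.29 (adjusted p = 0.000222). Esm1 rose by 5.0 ± 0.54 (adjusted p = 0.000717), the chemokine gene Ccl5 by 3.36 ± 0.29 and Eomes from 27.4 ± 14.4 to 251 ± 76.0 CPM, a fold of 9.86 (adjusted p = 0.00289). Il10, an anti-inflammatory cytokine gene, rose from 2.16 ± 2.97 to 27.3 ± 0.886 CPM (log2 change 3.42 ± 0.58, adjusted p = 0.00489; 6.19 without Control 2). Of 17 type 1 regulatory T cell genes 11 rose (13 higher and 2 lower when adjusted over the list alone), including Maf by 1.75 ± 0.24, Prdm1 by 1.45 ± 0.25 and Batf by 1.16 ± 0.16, with an adjusted p = 0.144 for the list with an estimated correlation and 0.0269 by fry. Of 16 cytotoxic genes 7 rose (7 when adjusted over the list alone; adjusted p = 0.169 with an estimated correlation, 0.0313 by fry), Prf1, the perforin gene, by 1.95 ± 0.25. Of 13 checkpoint genes 6 rose (8 higher and 1 lower when adjusted over the list alone; 0.338 with an estimated correlation), Tox by 1.44 ± 0.17 (adjusted p = 0.00109). Of 10 naive or memory genes 9 fell (9 when adjusted over the list alone; 0.144 with an estimated correlation, 0.0269 by fry), Tcf7 by 2.08 ± 0.30, Ccr7 by 1.99 ± 0.28, Satb1 by 1.65 ± 0.25 and Il7r by 1.52 ± 0.18.

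Further genes of the CD4 T-like cells followed the same split. Lag3 rose by 1.89 ± 0.42 (adjusted p = 0.0182; 0.0812, 0.0671 and 0.0565 without Control 1, 2 and 3 and 0.104 without Resistant 1; 1.25e-34 to 0.104 over its alternatives). Ifng rose by 1.90 ± 0.48 (adjusted p = 0.0298; 0.12, 0.0905 and 0.0843 without Control 1, 2 and 3 and 0.0626 and 0.123 without Resistant 1 and 2; 2.68e-32 to 0.123 over its alternatives). Foxp3 fell by 1.69 ± 0.37 (adjusted p = 0.0166; 0.0658 without Control 1 and 0.0531 without Control 3). Il2ra fell by 1.26 ± 0.26 (adjusted p = 0.0136; 0.0588 without Control 2 and 0.0524 without Control 3). Il1rl1 fell by 1.59 ± 0.33 (adjusted p = 0.0143; 0.0565 without Control 1 and 0.0529 without Control 3). These were the 3 called of 10 regulatory T cell genes (3 when adjusted over the list alone; list adjusted p = 0.517 with an estimated correlation). These falls may reflect the mix: regulatory T-like cells were 1.80% of Control and 1.93% of Resistant cells, other CD4 T-like cells 4.47% and 16.2%. Pdlim4 fell by 2.81 ± 0.34 (adjusted p = 0.00131), Pdlim1 by 2.29 ± 0.34, St6gal1 by 2.15 ± 0.31 and Dapl1 by 2.44 ± 0.42 (adjusted p = 0.00541; 0.0563 without Resistant 2). Irf7 rose by 1.74 ± 0.16, Ifit3 by 2.62 ± 0.25 and Isg15 by 1.71 ± 0.28 (145 ± 44.6 CPM, adjusted p = 0.00460). Of 17 MHC class I genes 10 rose (14 when adjusted over the list alone; 0.144 with an estimated correlation), H2-T22 by 0.93 ± 0.14, and of 12 proliferation genes 2 rose (3 when adjusted over the list alone; 0.187 with an estimated correlation), Top2a by 1.33 ± 0.21. A pair of clusters held many of these cells in Resistant 1 and 2, with 428 and 1197 cells in the larger and 473 and 141 in the other, against at most 39 and 18 in any other library. Cd8a, a CD8 T cell marker, stood at 74.5 and 39.9 CPM in the CD4 T-like cells of Resistant 1 and 2 against 1137 and 734 in their CD8 T-like cells, whereas Gzmk stood at 542 and 680 against 172 and 147.

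**Figure D4:**
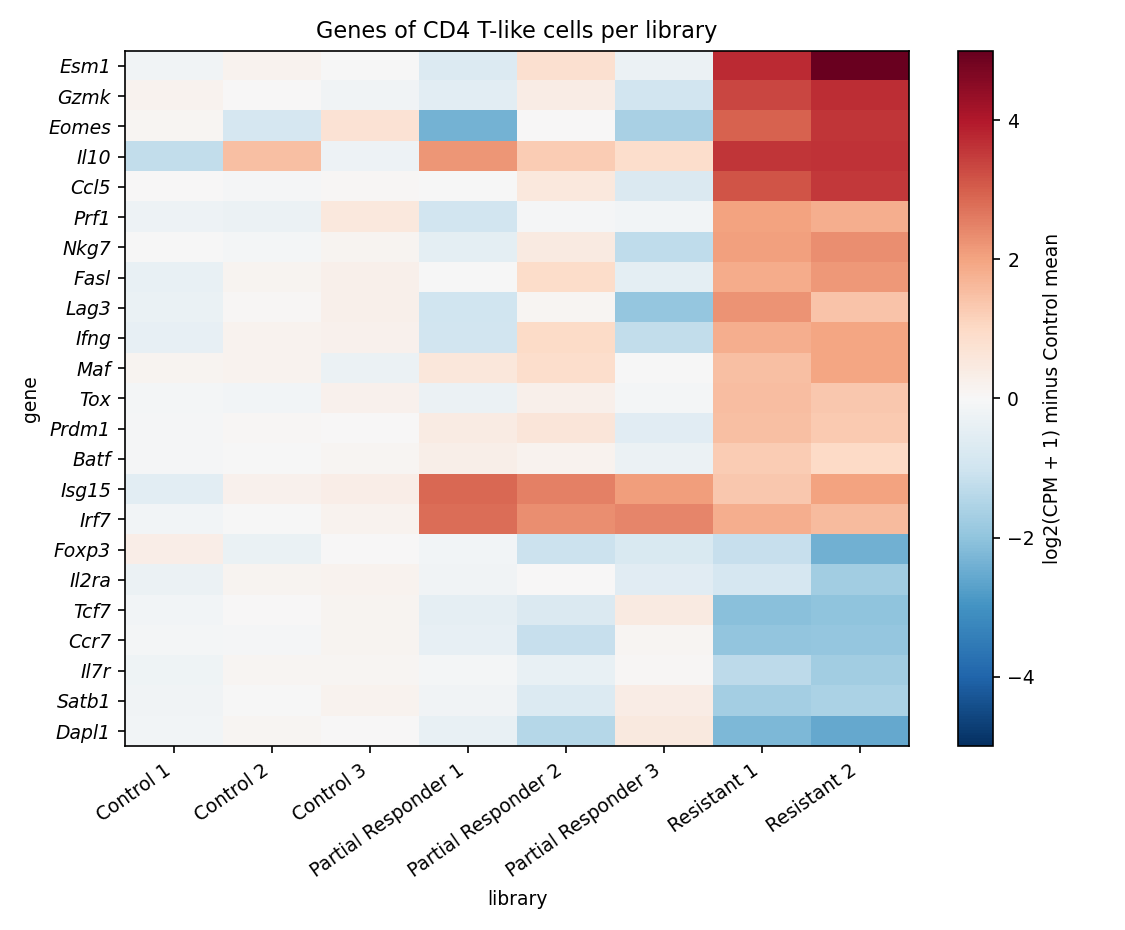
Change of log2(CPM + 1) from the Control mean (colour) for genes (y axis) in CD4 T-like cells of each library (x axis). Gzmk, Eomes, Esm1 and Ccl5 were highest and Tcf7 and Ccr7 lowest in Resistant 1 and 2, while Isg15 and Irf7 were higher than Control in all 5 treated libraries.

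Epithelial tumour-like cells of Resistant livers differed from Control in 9 of 10013 genes, 2 higher and 7 lower (673 at an unadjusted p under 0.05, and DESeq2 called 61). Within the cluster of large epithelial cells alone 111 genes were called. The count was 4 without Control 1, 16 without Control 2, 3 without Control 3, 29 and 25 without Partial Responder 2 and 3, and 19 and 4 without Resistant 1 and 2. Krt17, a keratin gene (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029, minus strand), fell from 114 ± 39.7 to 0.606 ± 0.857 CPM, a log2 change of -6.74 ± 0.59 (adjusted p = 0.00134). Ccl2 rose by 3.75 ± 0.33 (adjusted p = 0.00134). The remaining named calls rested on particular libraries. Meis2 fell by 6.38 ± 0.66 (adjusted p = 0.00433; 0.117 without Resistant 1). Ptn fell by 6.73 ± 1.01 (adjusted p = 0.0470; 0.0665 without Control 1, 0.108 without Control 3, 0.145 without Resistant 2, and a change of -10.96 at 0.178 without Resistant 1). Hspb1 fell by 4.46 ± 0.57 (adjusted p = 0.0188; 0.0529 and 0.0524 without Control 1 and 3 and 0.132 and 0.0530 without Resistant 1 and 2). Notum, a secreted Wnt antagonist gene, fell by 2.96 ± 0.38 (adjusted p = 0.0188; 0.0532 and 0.0835 without Control 1 and 3 and 0.129 and 0.0909 without Resistant 1 and 2). Irf7 rose by 2.28 ± 0.33 (adjusted p = 0.0411; 0.118 and 0.135 without Control 1 and 3 and 0.101 without Resistant 2). Over all alternatives the highest adjusted p was 0.0347 for Krt17, 0.0868 for Ccl2, 0.251 for Meis2, 0.221 for Ptn, 0.132 for Hspb1, 0.129 for Notum and 0.135 for Irf7. Of 35 interferon response genes 1 rose (30 when adjusted over the list alone; median 1.55, adjusted p = 0.116 with an estimated correlation), and Isg15 changed by 1.97 ± 0.34 to 165 ± 41.7 CPM (adjusted p = 0.0597; a change of 2.43 at 0.0171 without Control 2). All 17 MHC class I genes had a positive change and 0 passed (0 when adjusted over the list alone; adjusted p = 0.285 with an estimated correlation; median 0.46, and 0.26 without Resistant 2), with H2-K1 at 0.59 ± 0.21, B2m at 0.23 ± 0.20 and Mki67 at -0.23 ± 0.29. Of 11 Wnt genes Notum alone fell (6 when adjusted over the list alone; adjusted p = 0.116 with an estimated correlation).

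**Figure D5:**
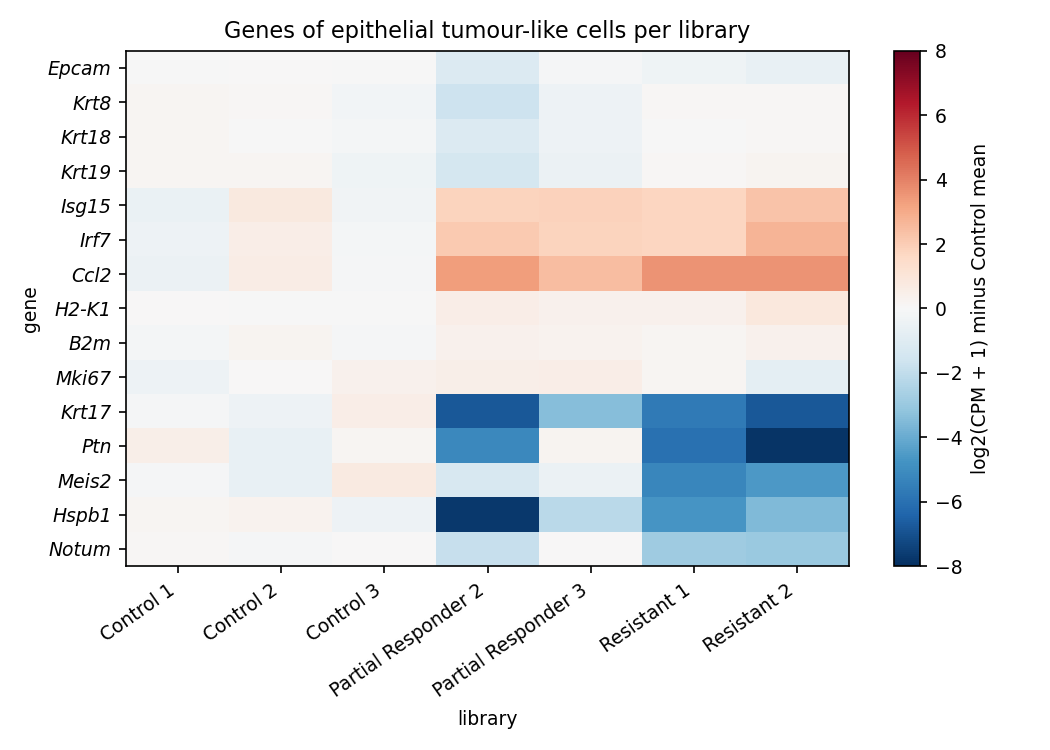
Change of log2(CPM + 1) from the Control mean (colour) for genes (y axis) in epithelial tumour-like cells of each library with enough such cells (x axis). Krt17 was lower and Ccl2 and Irf7 higher in the 4 treated libraries than in Control, whereas Ptn and Notum in Partial Responder 3 stayed near Control. Partial Responder 2 rests on 2 large and 25 small epithelial cells.

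Other classes of Resistant livers again rose in interferon genes and in genes outside that list. B-like cells had 271 of 10945 genes called (214 higher, 57 lower; 175 without Control 1, 161 without Resistant 1 and 154 without Resistant 2), and T cell markers rose with them. Of 8 such markers 4 rose (6 when adjusted over the list alone; adjusted p = 0.207 with an estimated correlation), beside Gzmk, up by 4.51 ± 0.59 (92 against 4 UMIs, adjusted p = 0.000528) and Arg1 by 2.75 ± 0.56 (adjusted p = 0.0193; 0.0894 without Control 3 and 0.255 without Resistant 1). NK or ILC1-like cells had 94 of 9227 (93 higher, 1 lower), Ifi27l2a up by 6.02 ± 0.21 and Gzmb by 0.76 ± 0.10 (adjusted p = 0.000709). Neutrophil-like cells had 82 of 8843, all higher (44 without Control 1, 31 without Resistant 1 and 45 without Resistant 2). In them Ifit3 was up by 4.96 ± 0.30. cDC-like cells had 225 of 9436 (183 higher, 42 lower; 134 without Control 1, 126 without Control 2, 371 without Partial Responder 1 and 99 without Resistant 2). Ccl24 rose by 6.23 ± 0.95 (adjusted p = 0.00477; a change of 12.92 without Control 1, and of 4.73 at 0.0550 without Resistant 2), Arg1 by 4.17 ± 0.85 (adjusted p = 0.0279; 0.0734, 0.134 and 0.0995 without Control 1, 2 and 3 and 0.246 without Resistant 2), Phlda3 by 2.99 ± 0.47 and Cdkn1a by 1.72 ± 0.21. Ccl24 and Arg1 also mark a finer macrophage-like cluster (177 and 132 cells in Resistant, 12 to 24 in Control libraries). Its RNA was not excluded: C1qb (15.6 CPM here, 21.3 in Control) marks another. Of 8 p53 targets in cDC-like cells 3 rose (5 when adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). MHC class I genes rose in 10 of 17 in B-like (0.0797 with an estimated correlation), 8 of 17 in cDC-like (0.109), 5 of 17 in NK or ILC1-like (0.0829) and 5 of 17 in neutrophil-like cells (0.408).

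No class passed in shares of cells between Resistant and Control livers. CD4 T-like cells, here without regulatory T-like cells, came nearest, at 16.2% ± 1.5 (SD, n = 2) against 4.47% ± 2.09 (n = 3), a log2 change of 1.86 ± 0.55 (adjusted p = 0.137; 0.0369 without Control 2; 0.0339 to 0.749 over its alternatives). Neutrophil-like cells took 3.06% ± 0.599 against 7.16% ± 1.99 (adjusted p = 0.264), and epithelial tumour-like cells 1.98% ± 1.37 against 1.19% ± 0.164. With 2 libraries against 3 an exact permutation test cannot reach a p under 0.05.

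Many of the genes called against Control were shared by both treated groups, which have the same 3 Control libraries. In macrophage and monocyte-like cells 422 genes were higher and 246 lower in both comparisons, where independent ones would share 36.5 and 15.5. Simulated data with shared controls and no effects averaged 0.1 and 0, but had too few calls to compare. The real numbers were 175 higher and 17 lower in B-like cells, 130 and 11 in cDC-like, 90 and 0 in NK or ILC1-like, 72 and 4 in CD4 T-like, 72 and 0 in neutrophil-like and 49 and 0 in CD8 T-like cells. The covariance of the log2 changes between the comparisons was 0.279 in macrophage and monocyte-like cells against 0.0436 simulated, 0.094 against 0.0504 in CD4 T-like and 0.0583 against 0.0582 in CD8 T-like cells. Since 3 Control libraries cannot be split into separate controls, part of any excess may come from sharing them.

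Resistant livers were last compared with Partial Responder livers, the test of what differed between treated mice by tumour volume. CD4 T-like cells held nearly all the called genes, with Eomes, Gzmk, Il10, Lag3 and 7 of 16 cytotoxic genes higher and 9 of 10 naive or memory genes and 14 of 34 interferon genes lower in Resistant livers. With an estimated correlation the adjusted p of these lists was 0.154, 0.169 and 0.151. In edgeR 0 genes passed in macrophage and monocyte-like, CD8 T-like, epithelial tumour-like and neutrophil-like cells (DESeq2 called 41, 57, 6 and 0), and few did in NK or ILC1-like, B-like and cDC-like cells. No share of cells passed.

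CD4 T-like cells differed in 752 of 9553 genes, 368 higher and 384 lower in Resistant livers, with 441 without Partial Responder 1, 478 without Partial Responder 3, 448 without Resistant 1 and 248 without Resistant 2. Eomes rose from 12.3 ± 11.5 to 251 ± 76.0 CPM, a fold of 19.1 (log2 change 4.25 ± 0.49, adjusted p = 0.00105), and Gzmk from 43.1 ± 21.6 to 598 ± 104 CPM (3.77 ± 0.29, adjusted p = 0.000184). Esm1 rose by 4.79 ± 0.47 and Rasd2 by 4.01 ± 0.56 (adjusted p = 0.00269; a change of 7.43 at 0.000130 without Partial Responder 2). Of 17 type 1 regulatory T cell genes 10 rose and Cd226 fell, by 1.68 ± 0.28 (12 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.154 with an estimated correlation, 0.0261 by fry). Il10 rose by 2.21 ± 0.45 (adjusted p = 0.0134; 0.0866 without Resistant 2; 1.45e-15 to 0.250 over its alternatives), Lag3 by 2.6 ± 0.42 and Batf by 1.08 ± 0.16. Of 16 cytotoxic genes 7 rose and 1 fell (9 and 2 when adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), Nkg7 by 2.46 ± 0.36 and Fasl by 1.75 ± 0.29. Of 13 checkpoint genes 7 rose (9 when adjusted over the list alone; 0.191 with an estimated correlation, 0.0367 by fry), Tox by 1.47 ± 0.16 (adjusted p = 0.000910), Nr4a2 by 2.78 ± 0.46 and Entpd1, the CD39 gene, by 1.57 ± 0.28. Ifng rose by 1.93 ± 0.46 (adjusted p = 0.0271), a call lost without Control 3 (0.051), Partial Responder 1 (0.0860), Partial Responder 3 (0.0519), Resistant 1 (0.0619) or Resistant 2 (0.112), while without Partial Responder 2 the change was 3.02 (6.80e-05; 8.17e-36 to 0.112 over its alternatives).

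The 384 genes lower in the CD4 T-like cells of Resistant than of Partial Responder livers included naive or memory genes and interferon genes. Of 10 naive or memory genes 9 fell (9 when adjusted over the list alone; list adjusted p = 0.169 with an estimated correlation), Tcf7 by 1.92 ± 0.29, Satb1 by 1.55 ± 0.25 and Il7r by 1.38 ± 0.18. Cd40lg, a helper T cell ligand gene, fell by 2.33 ± 0.27, Axin2 by 1.56 ± 0.23, Dapl1 by 2.19 ± 0.41 (adjusted p = 0.00975; 0.0892 without Resistant 2) and Itga1 by 2.16 ± 0.46 (adjusted p = 0.0165; 0.0545 without Partial Responder 1 and 0.133 without Resistant 2). Of 34 interferon response genes 14 fell (28 when adjusted over the list alone; median -0.66, adjusted p = 0.151 with an estimated correlation, 0.0201 by fry), among them Slfn5 by 1.61 ± 0.16 (adjusted p = 0.000756), Ifit3b by 1.86 ± 0.23 and Oasl2 by 1.45 ± 0.20. Isg15 changed by -0.81 ± 0.26 (adjusted p = 0.0896; a change of -0.99 at 0.0443 without Partial Responder 3; 1.24e-05 to 0.439 over its alternatives). Foxp3 changed by -1.06 ± 0.36 (adjusted p = 0.105; a change of -1.84 at 0.0163 without Resistant 1; 6.55e-09 to 0.493 over its alternatives), and 1 of 10 regulatory T cell genes fell (3 when adjusted over the list alone; list adjusted p = 0.0926, and 0.628 with an estimated correlation).

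Macrophage and monocyte-like cells had 0 in edgeR, 761 at an unadjusted p under 0.05 and 41 in DESeq2 (2 without Partial Responder 1 and 7 without Resistant 2). Mrc1 changed by 2.44 ± 0.63 (adjusted p = 0.399; 0.0786 to 1.00 over its alternatives), Arg1 by 2.00 ± 0.99 (0.728), Spp1 by 1.24 ± 0.72 (0.805), Isg15 by -0.12 ± 0.35 and Irf7 by -0.16 ± 0.12 (0.893). The chemokine genes Cxcl9 and Cxcl10 changed by -0.62 and -0.28. Of 18 pro-tumour macrophage genes 17 had a positive change (median 0.97, and 0.21 without Resistant 1) and 0 passed (6 when adjusted over the list alone; list adjusted p = 0.211 with an estimated correlation). The interferon response list had 4 of 35 genes with a positive change, a median of -0.09 and 0 called (0 when adjusted over the list alone). Its adjusted p was 0.0384, lost without Partial Responder 1 (0.235), Partial Responder 3 (0.110), Resistant 1 (0.125) or Resistant 2 (0.109), and 0.772 with an estimated correlation (2.90e-07 to 0.772 over its alternatives).

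CD8 T-like cells had 0 genes called in edgeR between Resistant and Partial Responder livers, 1055 at an unadjusted p under 0.05 and 57 in DESeq2. The count was 152 without Partial Responder 2, 2 without Partial Responder 3 and 19 without Resistant 2. Gzmb changed by 0.64 (adjusted p = 0.594), Ifng by 1.01 (0.620) and Pdcd1 by 1.59 ± 0.55 (0.380; 0.00779 to 0.999 over its alternatives). Isg15 changed by -0.96 ± 0.26 (0.327; 0.00554 to 0.999 over its alternatives). Of 13 checkpoint and exhaustion genes 0 passed (11 higher when adjusted over the list alone; median 1.28, and 0.66 without Resistant 1; list adjusted p = 0.339 with an estimated correlation). Of 34 interferon response genes 0 passed (15 lower when adjusted over the list alone; median -0.43, 0.339 with an estimated correlation). The clusters behind the class differed here too, 1 of them with 37, 158 and 9 cells in Partial Responder 1 to 3 and 414 and 142 in Resistant 1 and 2.

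In epithelial tumour-like cells 0 genes were called with 2 libraries on each side, 375 at an unadjusted p under 0.05 and 6 in DESeq2 (1 without Control 3 and 11 without Partial Responder 2). The test recovered 53.5% of simulated genes at a 4-fold change and 4% at 2-fold. Isg15 changed by 0.20 ± 0.37, H2-K1 by 0.15 ± 0.23, B2m by -0.09 ± 0.23 and Mki67 by -0.69 ± 0.34. The interferon response list had a median of 0.32 (adjusted p = 0.978 with an estimated correlation). Krt17 stood at 0 and 9.47 CPM in Partial Responder 2 and 3 and at 1.21 and 0 CPM in Resistant 1 and 2, while Partial Responder 3 had 267 CPM of Ptn, 37.9 of Meis2 and 140 of Notum.

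Of the remaining classes, B-like cells had 1 called gene between Resistant and Partial Responder livers (393 at an unadjusted p under 0.05, 7 in DESeq2, and 3 in edgeR without Partial Responder 1), Zrsr1, a splicing factor gene, higher by 1.06 ± 0.10 (adjusted p = 0.00114). Over all cells pooled, Zrsr1 stood at 24.7 and 23.1 CPM in Resistant 1 and 2 and at 9.19 to 14.4 CPM in the other libraries, so the change was not particular to B-like cells. NK or ILC1-like cells had 7, 3 higher and 4 lower (779 at an unadjusted p under 0.05 and 29 in DESeq2), among them Zrsr1 higher by 1.42 (adjusted p = 0.0421), Serpinb9b by 1.39 (0.0337) and Lpin1 by 0.87 (0.0421), and Maf with a change of -0.86 (0.0421). That count was 0 without Control 1, Partial Responder 3 or Resistant 2, 11 without Control 2, 37 without Control 3, 94 without Partial Responder 1, 3 without Partial Responder 2 and 1 without Resistant 1. cDC-like cells had 11, all higher (902 at an unadjusted p under 0.05 and 55 in DESeq2), among them Ccl24 by 7.79 ± 0.86 (adjusted p = 0.0203; 0.0990 without Control 1 and 0.0607 without Partial Responder 3), Cdh1 by 2.89 (0.0250) and Cd14 by 2.07. Ccl24 and Cd14 also mark that macrophage-like cluster, whose RNA was not excluded. Their count was 0 without Control 1 or Partial Responder 3, 2 without Control 2, 3 without Control 3, 69 without Partial Responder 1, 5 without Partial Responder 2 and 4 without Resistant 1. Neutrophil-like cells had 0 (168 at an unadjusted p under 0.05 and 0 in DESeq2).

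No class passed in shares of cells between Resistant and Partial Responder livers either. CD4 T-like cells, without regulatory T-like cells, took 16.2% ± 1.5 against 5.92% ± 1.09, a log2 change of 1.45 ± 0.54 (adjusted p = 0.0909; 0.0411 without Control 2; 0.0411 to 0.305 over its alternatives). Endothelial-like cells took 0.164% ± 0.202 against 2.40% ± 1.24, a change of -3.87 (adjusted p = 0.0906; 0.0427 without Control 2 and 0.00912 without Partial Responder 1; 0.00912 to 0.305 over its alternatives). cDC1-like cells took 0.393% ± 0.044 against 1.82% ± 0.213, a change of -2.20 (adjusted p = 0.0906; 0.0111 without Control 2 and 0.0429 without Partial Responder 1; 0.0111 to 0.305 over its alternatives). pDC-like and Kupffer-like cells changed by -2.21 and -1.93, each at an adjusted p of 0.0909 and at 0.0411 without Control 2 (0.0127 to 0.305 and 0.0411 to 0.305 over their alternatives).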

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

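The tests of RNA from other cells within parts of the immune classes, of CD8 T or NK cells counted as CD4 T cells, and of dilution of tumour-cell RNA were chosen after the results were seen. Resistant and Partial Responder livers, given the same kind of vector, differed by a direct test in 752 genes in CD4 T-like cells, 11 in cDC-like cells, 7 in NK or ILC1-like cells and 1 in B-like cells. The B-like gene, Zrsr1, was higher in Resistant livers over all cells pooled too, and a strain variant was not tested and stays open for it. Outside the gene comparisons, the vector segments MRC1p and dR3RU6 had 7 and 5 UMIs in libraries given the interferon-alpha vector and 0 in Control libraries. Each exceeded every Control library in 2 of 5 treated libraries, while the segment LVrest had 4 UMIs in treated and 3 in Control libraries and HIVintegration, with the most UMIs, went the other way, with 6 and 13.

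Interferon response genes were higher in the 7 immune classes of treated livers. Library depth stays untested: thinning to equal totals left at least 95% of the list's median change, but would do so whatever its cause. RNA from other cells is argued against for macrophage and monocyte-like, B-like, neutrophil-like and cDC-like cells, which would need at least 2.449 times the foreign RNA that the markers of other classes allow. It is argued against as well for T and NK cells taken as 1 family, which would need at least 6.434 times the RNA from outside the family that the markers allow. Within that family the lowest ratio was 0.482, so that an exchange of RNA among CD8 T-like, CD4 T-like and NK or ILC1-like cells, which share markers, cannot be told apart from a response in each. The interferon-alpha vector, which the design names, stays among the open explanations, as untested.

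In CD4 T-like cells of Resistant livers 7 of 16 cytotoxic and 11 of 17 type 1 regulatory genes rose against Control, with adjusted p = 0.169 and 0.144 for the lists with an estimated correlation. CD8 T or NK cells counted as CD4 T cells, or their RNA, are argued against, since the genes would need at least 14.094 times the CD8 T or NK RNA that Cd8a, Cd8b1 and NK markers allow. Much of the pattern rested on 2 clusters found almost only in Resistant livers. Without them 12.4% of the median change against Control was left over 17 cytotoxic, type 1 regulatory or checkpoint genes called in both comparisons. Then 76 genes were called in place of 945, and 0 in place of 752 against Partial Responder livers. Gzmk kept 48.2% and Eomes 39.4% of the change against Control and Eomes 62.8% against Partial Responder, all uncalled. Those clusters were formed partly from the same genes, so this says where, not why, the change lay. The difference in outcome between the treated mice stays open, untested.

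Krt17, Ptn, Meis2, Hspb1 and Notum were lower in epithelial tumour-like cells of Resistant livers. A change in the mix of the 2 epithelial clusters is argued against as the whole cause by the cluster of large cells, where all 5 genes were lower, with a median log2 ratio of -5.72 and adjusted p from 3.63e-06 to 0.000177. The cluster of small cells argues little either way: its median ratio was -2.16, but Krt17 rested on 0 against 1 UMI and Meis2 on 2 against 5, Notum had an adjusted p of 0.212 and Hspb1 was higher, with 19 against 2 UMIs. Dilution by RNA from other cells is argued against too, since 12 epithelial markers had a median change of 0.02 with a spread of 0.23 (SD), 6.40 above that of the 5 genes. A difference between the tumour cells of the mice stays open and was not tested, and Resistant 1 and 2 had only 82 and 10 cells in the cluster of large cells.

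The 6 Control and Partial Responder libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In each of 7 immune classes 1 of the 10 splits, the real one, gave as many genes. The real count and the highest of the others were 1089 and 1 in macrophage and monocyte-like cells, 231 and 0 in B-like, 208 and 1 in cDC-like, 191 and 1 in NK or ILC1-like, 100 and 0 in CD8 T-like, 97 and 1 in CD4 T-like and 80 and 2 in neutrophil-like cells. For shares of cells, 1 split, the real one, gave as many classes (2, and 0 as the highest of the others). Counts of gene lists at the preset correlation were as large in 10 splits in CD8 T-like (8 real, 13 highest other), 9 in CD4 T-like (6 and 13), 8 in NK or ILC1-like (6 and 10), 7 in macrophage and monocyte-like (8 and 14), 6 in B-like (8 and 16), 5 in neutrophil-like (9 and 16) and 5 in cDC-like cells (8 and 9).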

How the results depend on the processing

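The tests of macrophages alone, of monocytes alone and of CD4 T-like cells without regulatory T cells were chosen after the results were seen. Among 232 values of named genes, 186 of them called, side of the threshold, and direction if called, held for 232 with RLE. They held for 224 at resolution 0.5, 221 with doublets kept, 220 without a filter on low counts and 219 with DESeq2. They held for 197 without Control 1, 203 without Control 2 and 198 of 227 without Control 3. Without Partial Responder 1, 2 and 3 they held for 195 of 213, 212 and 210, and without Resistant 1 and 2 for 206 and 195 of 227. They held for 41 of 64 in macrophages alone, 53 of 60 in monocytes alone and 69 of 75 without regulatory T cells. Where a left-out library leaves a class without enough libraries, no value was had.

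Counts of called genes moved by over 1.5 times in these and other cases, the cause untested unless given. Without a filter on low counts, which adds genes to the test, CD8 T-like cells had 278 genes between Partial Responder and Control in place of 100, 88 between Resistant and Control in place of 49, and 319 between Resistant and Partial Responder in place of 0. CD4 T-like cells then had 280 in place of 97, 1650 in place of 945 and 1453 in place of 752, epithelial tumour-like cells 140 in place of 0, 471 in place of 9 and 132 in place of 0, and macrophage and monocyte-like cells 30 between Resistant and Partial Responder in place of 0. DESeq2 called 183 genes in CD8 T-like cells between Partial Responder and Control, and between Resistant and Partial Responder 57 in CD8 T-like and 41 in macrophage and monocyte-like cells in place of 0. In epithelial tumour-like cells it called 13, 61 and 6 in place of 0, 9 and 0. With clusters at resolution 0.5, CD4 T-like cells had 527 genes between Resistant and Control. In macrophages alone 301 genes were called between Partial Responder and Control, not 1089, and 143 between Resistant and Control, not 950. That drops cells and the mainly Control monocyte-like cluster together.

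Leaving out each library in turn gave 524 to 958 genes in macrophage and monocyte-like cells between Partial Responder and Control, 292 to 1051 between Resistant and Control and 0 to 7 between Resistant and Partial Responder. The ranges in the same order were 63 to 215, 22 to 59 and 0 to 152 in CD8 T-like cells. In CD4 T-like cells they were 294 to 1133 between Resistant and Control and 248 to 1102 between Resistant and Partial Responder. In epithelial tumour-like cells they were 3 to 29 between Resistant and Control and 0 to 11 between Resistant and Partial Responder. Counts of classes with a changed share ranged from 0 to 3 between Partial Responder and Control (2 with all libraries), 0 to 1 between Resistant and Control and 0 to 5 between Resistant and Partial Responder (0 with all libraries in both). As shares of immune cells there were 1, 1 and 3 changed classes, with doublets kept 2 between Resistant and Partial Responder, and between Partial Responder and Control 0 with clusters at resolution 0.5 and 0 by exact permutation, which cannot pass at this size. The cause was not tested, other than for the permutation test.

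Nothing in the labels pairs the mice by replicate number, and the residuals gave no clear sign of it: in macrophage and monocyte-like cells, libraries of Control and Partial Responder with the same number had correlations of residuals across genes of 0.0299, -0.144 and 0.0491, and genes are not independent replicates. With the replicate number as a block, epithelial tumour-like cells had 33, 259 and 49 genes called over the 3 comparisons, macrophage and monocyte-like cells 614 between Resistant and Control and 1 between Resistant and Partial Responder, and CD8 T-like cells 30 and 2 in those comparisons. With the block 212 of the 232 gene values held, 17 lost and 3 gained a call, and 0 classes changed their share between Partial Responder and Control.

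Of the 234 list tests called at the preset correlation, 17 were called with an estimated correlation, which allows for genes that vary together. Some values reversed in sign, and the cause was not tested. In monocytes alone the median of the interferon response list between Resistant and Partial Responder was 0.087. There the inflammatory list was -0.51 between Partial Responder and Control and -0.18 between Resistant and Control, the pro-tumour list -0.30 between Resistant and Control, and Ccl2 changed by -0.16 between Partial Responder and Control. Leaving out libraries in turn, Cxcl10 in macrophage and monocyte-like cells changed by -0.58 to 3.94 between Resistant and Control, the highest without Control 2, which held far more of it than the other Control libraries. Without regulatory T cells, Trf in CD4 T-like cells changed by 0.66 between Partial Responder and Control. The number of cells, rather than depth, kept Partial Responder 1 out of the epithelial tumour-like comparison and several libraries out of those of Kupffer-like and endothelial-like cells.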

Other observations

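The tests of Kupffer-like and endothelial-like cells with a minimum of 5 cells per library, and of T cell clones, were chosen after the data were seen. Kupffer-like cells of Partial Responder livers differed from Control in 116 of 2465 genes, 64 higher (n = 3 and 3, 7 to 36 cells per library). The resident-macrophage genes Marco and Clec4f rose by 3.74 ± 0.80 and 1.67 ± 0.35 (adjusted p = 0.00945 and 0.00927), with Cd5l up by 1.99 and the iron exporter gene Slc40a1 by 1.63. Ccr2, a monocyte receptor gene, fell by 4.72 ± 0.60 (adjusted p = 0.000667), Cx3cr1 by 1.30, Il1b by 1.74 and the antigen-presentation genes Cd74 and H2-Aa by 1.72 each. Isg15 rose by 1.63 ± 0.37 (adjusted p = 0.0148) and Irf7 by 1.69. The hepatocyte gene Alb rose with them by 1.71 (adjusted p = 0.00945), and many ribosomal protein genes fell, Rplp0 by 1.42, Rpl36a by 1.19 and Rps12 by 1.14, so that RNA from other cells or a difference in RNA content was not excluded. In Resistant livers 9 genes differed from Control, with Irf7 up by 1.57 and Il1b down (a change of -2.32), while Clec4f changed by 0.20 (adjusted p = 0.933) and Marco by 2.20 (0.552). Between Resistant and Partial Responder livers 13 genes differed, with Ccr2 higher by 3.77, Cd74 by 1.42 and Slc40a1 changed by -1.84, while Clec4f changed by -1.47 (adjusted p = 0.111) and Marco by -1.54 (0.376).

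Endothelial-like cells of Partial Responder livers (n = 3) differed from 2 Control libraries, which held 19 and 5 such cells, in 23 of 9305 genes, 16 higher. The T cell attractants Cxcl9 and Cxcl10 rose there by 2.81 ± 0.41 (adjusted p = 0.0317) and 4.71 ± 0.70 (0.0343). Irf7 rose by 2.99 and Ifit3 by 4.45, while Isg15 (2.63, adjusted p = 0.0707) and H2-K1 (1.64, 0.0760) did not pass. The red-cell genes Hbb-bs and Hba-a1 had changes of -6.93 and -7.99, and whether these came from free RNA or from attached cells was not tested.

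The 2 clusters of CD4 T-like cells found almost only in Resistant livers may hold few expanded T cell clones. Receptor segments had been left out of clustering. In Resistant 1, Trbv20 made up 70 of 161 detections of Trbv segments in the clusters, 43.5% (95% Wilson interval 36.1% to 51.2%), against 12% in its other CD4 T-like cells, a ratio of 3.62. In Resistant 2, Trbv19 made up 310 of 387, 80.1% (75.8% to 83.8%), against 13.4%, and Trav13d-1 made up 71.2% of Trav detections against 1.15%, where in Resistant 1 the most frequent was Trav16n at 64.6% against 5.30%. The other libraries had 3 to 12 Trbv detections in these clusters, and the most frequent segment of so few has a high ratio by construction, so that they cannot serve as a comparison. Trbv19 led in Control 1 (4 of 8) and Partial Responder 2 (8 of 12) and Trbv20 in Control 2 (4 of 8), while other segments led in Control 3, Partial Responder 1 and Partial Responder 3, so that a bias in segment use of such cells stays open beside expanded clones.

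Some genes set single libraries or groups apart in all cells, for no reason tested. Coro1b stood at 18.3 CPM in Partial Responder 3 and at 3.26 to 7.90 in the other libraries. Zrsr1 stood at 24.7 and 23.1 in Resistant 1 and 2 and at 9.19 to 14.4 elsewhere, and Rps10 at 1156 and 1522 against 1833 to 2770.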
